A study of Rattus norvegicus with 8 samples.

How the data were processed

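H3K4me2 was measured by native chromatin immunoprecipitation and sequencing in sperm from the epididymides and vas deferens of 4 Fischer 344 rats. The labels pair the libraries: the sperm of each rat were divided into an IP sample and a genomic control sample. Per the labels' protocols the IP chromatin was cut with MNase for 10 minutes and pulled down with 5 ug of antibody. The control was extracted genomic DNA, for which the labels state no MNase, so IP and control differ in how the DNA was cut as well as in the antibody. Libraries were sequenced as 50 bp single reads on 2 lanes. Lane 8 held the IP libraries of AA1, MM1 and MM2 and the control of AA2, and lane 7 held the others, so the lane is tied to AA2 within the IP group.

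The deposited files list aligned reads, 1 per line, as a start and an end on a chromosome with a strand. Each span was 51 bp long. The deposited score column was 0 on every line and was not used. The submitters' processing notes name FastQC, Bowtie 1.1.2 and HOMER 4.9, with no roles or options, and 2 genome builds, rn4 and rn6. The names of the IP data give rn4. The last read on each chromosome lay within 1 kb of the same position in all 8 libraries, so all were read as rn4. How reads with several equally good places were treated is not given in the sources used here. Repeated positions were present in the files, so no removal of duplicates by the authors is assumed.

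The files hold no column of counts, so reads were counted here. A read position was used once per strand and library and moved 75 bp toward its 3' end. Reads were counted in windows of 1000 bp on chromosomes 1 to 20 and X. Library scales were the median ratios to the geometric mean over 243665 autosomal bins of 10 kb with reads in all libraries. This sets the typical bin to a log2 ratio of 0, so enrichment and depletion are relative to the background of the IP. Scaled reads are reads divided by this scale. Windows with at least 40 reads over the 8 libraries were tested.

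The test was limma-voom (limma 3.58.1, R 4.3.3) with a library size from the scale, the rat as a block and moderated variances. The prior degrees of freedom were 98.1, so SEs and p-values of windows rest mostly on a variance pooled over windows. They reflect the spread between the 4 rats in a single window only in small part. P-values were adjusted by the Benjamini-Hochberg method. A window was enriched at an adjusted p under 0.05 and a log2 ratio of at least 1, and depleted at a log2 ratio of -1 or below. The rat was a block because IP and control came from the same animal. Deviations of the IP and control library of a rat from their group means correlated at 0.0735 in AA1, -0.0627 in AA2, -0.126 in MM1 and 0.0129 in MM2, so the block rests on the labels and not on a shared deviation. The design had foreseen edgeR or DESeq2 only for files with a column of counts, and they were not run.

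The code was tested on simulated data: 100000 autosomal windows were drawn with the control means. The dispersion was 0.00482 for controls, from the spread among control libraries, and 0.0274 for the IP. The latter came from the spread among IP libraries in windows with the lower IP to control ratios. Of 60 windows raised 2-fold, the calling threshold itself, 51.7% were called, and all of the 70 raised 4-fold and the 70 raised 8-fold. Of the unchanged windows 8 were called enriched and 0 depleted. The spread between rats in enriched windows was not simulated, so these shares do not give the recovery among real enriched windows. No window was lowered in the simulation. The fit over all windows at once was checked against limma's own fit on real windows.

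Single values per library were compared by two-sided exact permutation tests over the 70 assignments of 4 of 8 libraries, whose smallest p is 0.0286. Sign flips within rats were the alternative. For shares of reads in regions, the regions were called without the rat in question, with at least 30 reads over 6 libraries. Counting error is given as 95% Wilson intervals. Reads carry no molecular identifiers, so intervals cover counting error only. Per-rat log2 ratios used a pseudocount of 0.5 reads. Distances between read starts were counted on chromosome 1 and smoothed over 11 bp (opposite strands) or 21 bp (same strand). Other computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

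Regions were named by a rule fixed before the data were examined: the 10 autosomal and the 5 X-linked regions with the largest mean log2 ratio among those with at least 5 control reads per kb and library, the 5 longest, and the 5 windows with the most negative log2 ratio past the threshold. Alternatives fixed at the same time changed the block, a lane term, duplicates, read shift, scaling, model, read minimum, thresholds, window size and joining distance, and left out each rat. Others were added after seeing the data: a control read minimum, a limit on strand balance, and leaving out X. The classes of region length and strand, the 1 Mb segments and the comparisons of X with autosomes were also chosen after seeing the data. Promoters, gene lists and the location of windows relative to genes were planned for an annotation of the same build and were not analysed here. The genome sequence was not used here, so GC content and mappability were not checked.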

Results

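Dimethylation of histone H3 at lysine 4 (H3K4me2), a mark found at promoters and other active regulatory sequence in many cell types, was mapped in mature sperm of 4 adult Fischer 344 rats, an inbred laboratory strain. Sperm package most of their DNA with protamines, so the question addressed was where nucleosomes that carry this mark remain along the sperm genome. The rats had received only the vehicle of an exposure study. Each rat, named AA1, AA2, MM1 or MM2, gave an H3K4me2 immunoprecipitate (IP) from 10000000 sperm, released by 10 minutes of micrococcal nuclease (MNase) digestion, and a genomic control library from 4000000 sperm. The IP libraries held 29035697 to 37544507 aligned reads and 21112141 to 27721756 distinct read positions. The control libraries held 24117776 to 41665030 reads and 23722374 to 40867931 distinct positions. Reads at an already used position made up 22.5% ± 7.72 of IP reads and 1.84% ± 0.164 of control reads (SD, n = 4 each), and the comparisons below used distinct positions unless all reads are named.

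The H3K4me2 IP was enriched over control DNA in many short, separate places. IP and control differ in how the DNA was cut as well as in the antibody. The ratio alone therefore cannot assign a place to the mark and not to the cutting. Of 2431677 windows of 1 kb tested, 187367 (7.71%) were enriched at least 2-fold, with a median log2 ratio of 1.78 and quartiles of 1.31 and 2.46. At least 4-fold enrichment was found in 76340 windows, 40.7% of those enriched. Joined across gaps of up to 1 kb, enriched windows formed 59646 regions that covered 194.4 Mb, with a median length of 2000 bp and quartiles of 1000 and 4000 bp. An enriched window had another directly beside it in 84.6% of cases, against 14.8% for a random placement.

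The log2 ratio was higher in longer regions up to 19 kb. The 23189 regions of a single window had a median log2 ratio of 1.24, and 84.7% of them lay above control in all 4 rats. The 23387 regions of 2 to 4 kb had a median of 1.77, the 9939 regions of 5 to 9 kb 2.05, and the 2781 regions of 10 to 19 kb 2.20. The 350 regions of 20 kb or more also had a median of 2.20, covered 8.7 Mb and lay above control in all 4 rats in 100% of cases. Length and ratio came from the same libraries here, and a stronger signal gives longer runs of called windows. In regions called from the other 3 rats, the median in the rat left out went from 1.06 at 1 kb to 2.28 at 10 to 19 kb in AA1, from 0.21 to 1.39 in AA2, from 1.68 to 2.67 in MM1 and from 1.32 to 3.06 in MM2, and at 20 kb or more it was 2.32, 1.46, 2.64 and 3.03. Of the 1 kb regions called from the other 3 rats, 89.9% lay above control in AA1, 61.2% in AA2, 94.8% in MM1 and 89.5% in MM2. At 20 kb or more the share was 99.8% in AA2 and 100% in AA1, MM1 and MM2. The region sets differed between rats, with 32937 regions of 1 kb for AA2 and 18319 to 21623 for the others. The window test was limma-voom with the rat as a block and Benjamini-Hochberg adjustment.

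The longest enriched region spanned 60 kb of chromosome 10, from 85000001 to 85060000 (rn4), with 54 of its 60 windows enriched. It held 41.3 ± 15.4 scaled IP reads per kb against 8.78 ± 1.08 in the controls (SD, n = 4), a log2 ratio of 2.15 ± 0.73. Within it the signal was uneven and highest at 85026001 to 85027000, where the IP libraries had 111 ± 33.6 scaled reads against a control mean of 8.68. Enrichment was lowest in AA2, with a log2 ratio of 1.11, and highest in MM1, with 2.82. Further enriched windows stood on both sides, 20 of them within the 20 kb flanks.

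**Figure D1:**
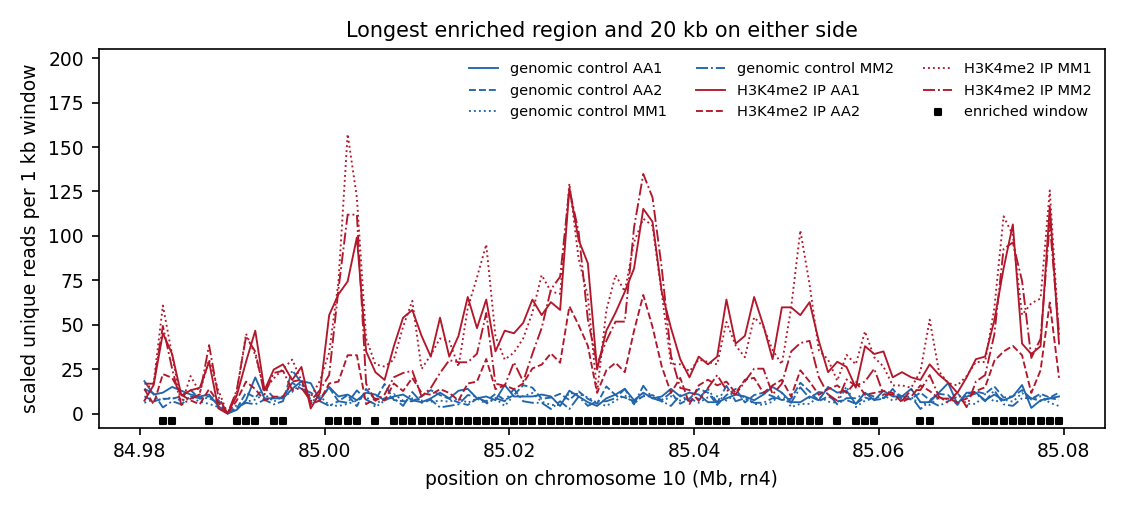
Scaled unique reads per 1 kb window (y axis) along chromosome 10 in Mb of build rn4 (x axis) for the 4 IP and 4 control libraries, with enriched windows as black squares. Within the 60 kb region the IP libraries averaged 41.3 scaled reads per kb and the controls 8.78, and AA2 had the lowest IP signal.

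The other 4 of the 5 longest regions were 42 to 46 kb long. They lay on chromosome 16 from 32434001 to 32480000 (log2 ratio 2.58 ± 0.45), chromosome 5 from 143157001 to 143201000 (2.74 ± 0.52), chromosome X from 79311001 to 79354000 (2.37 ± 0.38) and chromosome 1 from 192399001 to 192441000 (2.53 ± 0.36; SD over rats, n = 4). The regions on chromosomes 16 and 5 held 66.6 and 71.2 scaled IP reads per kb, and that on X 29.0, against 5.46 control reads per kb on X and 10.7 and 10.3 on the other 2.

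The strongest autosomal enrichment among regions with at least 5 control reads per kb and library was found on chromosome 10 from 53190001 to 53192000, at a log2 ratio of 4.31 ± 1.28 (SD, n = 4). This 2 kb region held 141 ± 53.4 scaled IP reads per kb against 7.13 ± 3.53 in the controls. The next was an 8 kb region on chromosome 20 from 25590001 to 25598000, with 190 ± 51.6 against 10.4 ± 2.28 scaled reads per kb and a log2 ratio of 4.17 ± 0.70. A region of 2 kb on chromosome 4 from 125163001 to 125165000 reached 3.86 ± 1.19, and a region of 2 kb on chromosome 11 from 44287001 to 44289000 reached 3.79 ± 0.28, the smallest spread of these 10. Chromosome 3 held 3 of the 10, at 148369001 to 148372000, 148378001 to 148380000 and 156274001 to 156276000, with log2 ratios of 3.88 ± 0.75, 4.04 ± 0.77 and 3.84 ± 1.23. The second of these held 88.1% plus-strand IP reads and the first 66.5%. The remaining 3 were single windows, on chromosome 2 at 5794001 to 5795000, with a mean of 3.82 and a range over rats of 2.36 to 4.94, and on chromosome 16 at 73523001 to 73524000 (3.78 ± 1.18) and 73133001 to 73134000 (3.84 ± 0.65).

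On chromosome X the 5 strongest regions ran from 113615001 to 113618000, 43394001 to 43398000, 117456001 to 117459000, 131588001 to 131590000 and 135573001 to 135576000. Their log2 ratios were 3.61 ± 0.68, 3.73 ± 0.64, 3.54 ± 0.38, 3.32 ± 0.72 and 3.34 ± 0.64 in that order (SD, n = 4). They held 44.4 to 68.8 scaled IP reads per kb, at least 10.3 times the control level in each. All 20 of these regions had a log2 ratio above 1 in each of the 4 rats, and in 18 of the 20 the ratio was lowest in AA2. The largest adjusted p of any enriched window in them was 0.0317 (limma-voom), in the 60 kb region. No gene annotation of rn4 was used here, so regions are given by position and not by gene.

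**Figure D2:**
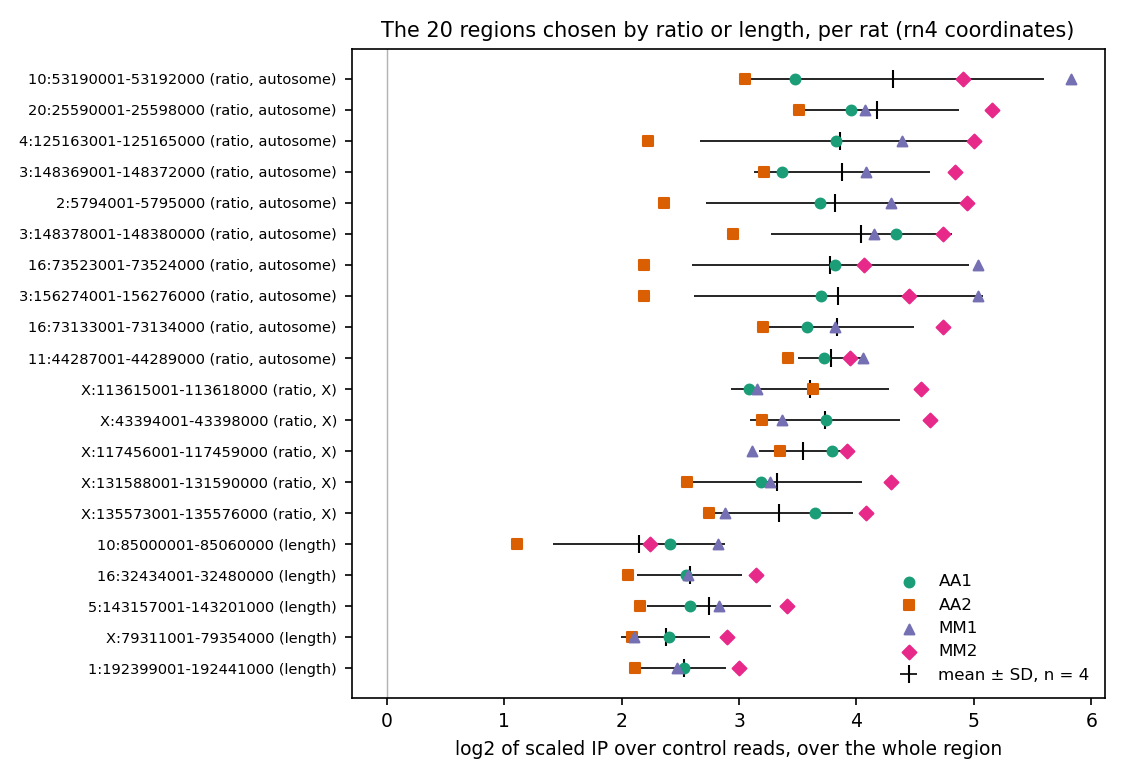
Log2 ratio of scaled IP over control reads (x axis) for the 20 regions chosen by ratio or length (y axis, rn4 positions), with a point for each rat and a bar for the mean ± SD, n = 4. All points lie above 1, the lowest being AA2 in the 60 kb region on chromosome 10 at 1.11.

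Few windows were called depleted in the IP relative to its background. Tested windows averaged 13.1 control and 10.1 IP reads per kb and library. Those called depleted averaged 17.2 and 3.7, and the power to call a loss was not simulated. By the same test 1193 windows (0.049%) had at least 2-fold fewer reads in the IP, with a median log2 ratio of -1.43, and none of them lay beside another, where a random placement would give 0.098%. The lowest was on chromosome 9 at 82549001 to 82550000, with a log2 ratio of -2.58 and a moderated SE of 0.65. There the SD over rats was 1.72 (n = 4), and the 4 IP libraries together held 5 reads against 44 in the controls. Others were on chromosome X at 76321001 to 76322000 (4 IP reads against 38) and 136408001 to 136409000 (5 against 40), on chromosome 8 at 17793001 to 17794000 (5 against 48) and on chromosome 16 at 29585001 to 29586000 (4 against 47). Their log2 ratios ran from -2.36 to -2.50. This count was not stable: it was 76 without MM2, 160 without AA1, 703 without AA2 and between the last 2 values without MM1, 774 with the sequencing lane in the fit, 2974 without the rat block and 10743 with limma-trend. Scaling by total reads moved the median log2 ratio of all windows to -0.31 and gave 25267 depleted and 139786 enriched windows. The share of enriched among called windows was then 84.7%, against 99.4% under the scaling used here.

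The H3K4me2 IP was enriched in each rat at the regions found in the other 3 rats. Regions called from 3 rats took up 5.75 to 9.09% of 1 kb windows and held 20.1 to 29.6% of the remaining rat's IP reads, against 5.73 to 9.90% of its control reads. The means were 25.1% ± 3.89 and 7.21% ± 1.91 (SD, n = 4), a difference of 17.9 percentage points, p = 0.0286 by a two-sided exact permutation test over 70 assignments of libraries, the smallest p it allows. Exact sign flips within rats gave p = 0.13, the smallest that 4 pairs allow. The region sets differed in size between rats, so these shares compare a rat's IP with its own control. The permutation test exchanges libraries between rats and so between region sets, while the sign flips keep to the pairs. The ratio of IP to control share was 3.46 in AA1, 2.03 in AA2, 4.50 in MM1 and 4.93 in MM2.

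In the single set of regions called from all 4 rats, and so from these same libraries, 26.8% of AA1, 18.3% of AA2, 29.2% of MM1 and 32.4% of MM2 IP reads were found, against 7.85%, 7.57%, 6.85% and 7.00% of the control reads in the same order. The 95% Wilson intervals were narrow, for example 18.26 to 18.29% for the AA2 IP and 32.38 to 32.42% for the MM2 IP, and cover counting error only. The libraries were sequenced on 2 lanes. Lane 8 held 3 IP libraries and 1 control and lane 7 the reverse, too few per lane for a test within lanes. With the lane beside the rat block in the limma-voom fit, 155274 windows were enriched.

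**Figure D3:**
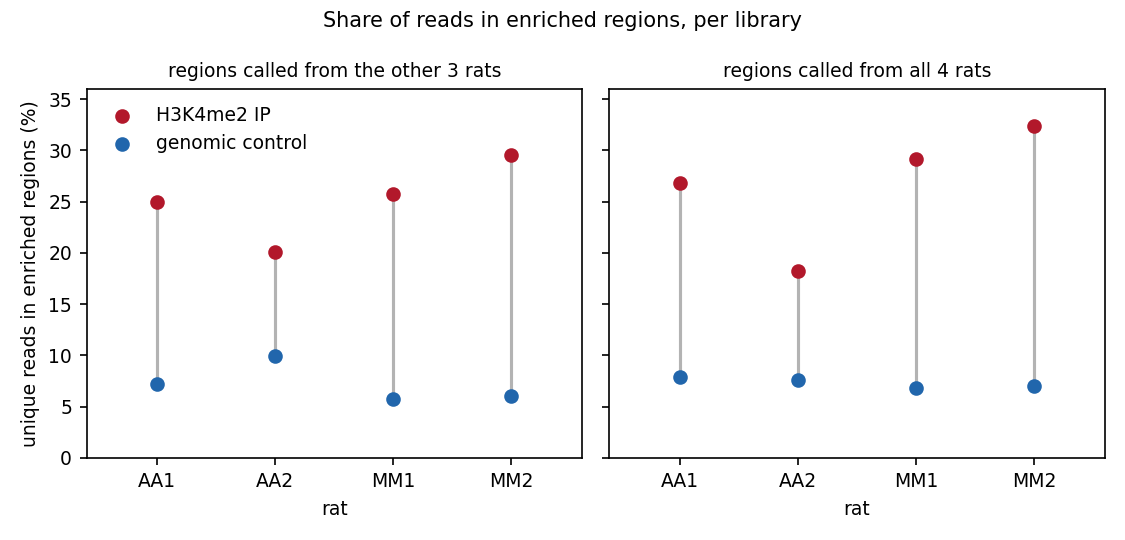
Percent of unique reads in enriched regions (y axis) for the IP and control library of each rat (x axis), with regions called from the other 3 rats on the left and from all 4 rats on the right. Each IP point lies above its control, and the AA2 pair is the closest together in both panels.

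Windows called in different rats overlapped more than independent lists would. By a two-sided binomial comparison of the IP and control library of each rat, at an adjusted p under 0.05 and a log2 ratio of at least 1, 100336 windows were called in AA1, 57894 in AA2, 196117 in MM1 and 150745 in MM2. This test covers counting error only. All 4 rats shared 50523 windows, 22% of the 229439 called in any rat, where independent lists would share 11.9. Across windows, which are not independent replicates, the log2 ratios of 2 rats correlated at r = 0.247 to 0.494, and at 0.335 to 0.622 in 2 kb windows. The 3 pairs with AA2 averaged 0.299 and the other 3 pairs 0.459. In windows called from the other 3 rats the median log2 ratio was 1.83 in AA1, 0.88 in AA2, 2.37 in MM1 and 2.45 in MM2. These sets differed: that for AA2 held 235594 windows, with a median of 1.77 in the rats that gave it. Those for the other rats held 150932 to 166199 windows, with medians of 1.84 to 1.95, so the values are not directly comparable between rats.

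Enriched windows were unevenly spread over chromosomes. Chromosome 12 had 153 per 1000 tested windows, chromosome 10 125, chromosome 20 121 and chromosome 19 104, against 53.3 on chromosome 2 and 58.1 on chromosome 13. The autosomes together had 77.7 per 1000 and chromosome X 64.0. Counted per Mb of chromosome, X was the lowest of all at 44.4, followed by chromosome 2 at 48.4. On X 69.3% of windows had enough reads to be tested, against 90.7% on the autosomes. In windows with balanced strands the control median was 6.75 reads per kb on X and 13 on the autosomes. Fewer reads leave less power to call a window, and the count per Mb takes untested windows as not enriched. The lower values on X therefore need not mean less of the mark. Chromosome 10 took 4.76% ± 0.43 of IP and 3.98% ± 0.22 of control reads, chromosome 12 2.05% ± 0.23 and 1.62% ± 0.15, and chromosome 2 8.95% ± 0.41 and 9.80% ± 0.33 (SD, n = 4). No difference in these percents passed the Benjamini-Hochberg adjustment over 22 sequences, the smallest adjusted p being 0.0786 by two-sided exact permutation tests. Before adjustment 8 had an exact permutation p of 0.0286, the smallest possible, and these included chromosome 20, higher in the IP of all 4 rats by 0.271 percentage points on average. A smallest p of 0.0286 passes the adjustment over 22 sequences only if many of them reach it together. The lack of calls therefore says little against a difference. Chromosomes 2, 10 and 12 each differed in the same direction in all 4 rats.

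**Figure D4:**
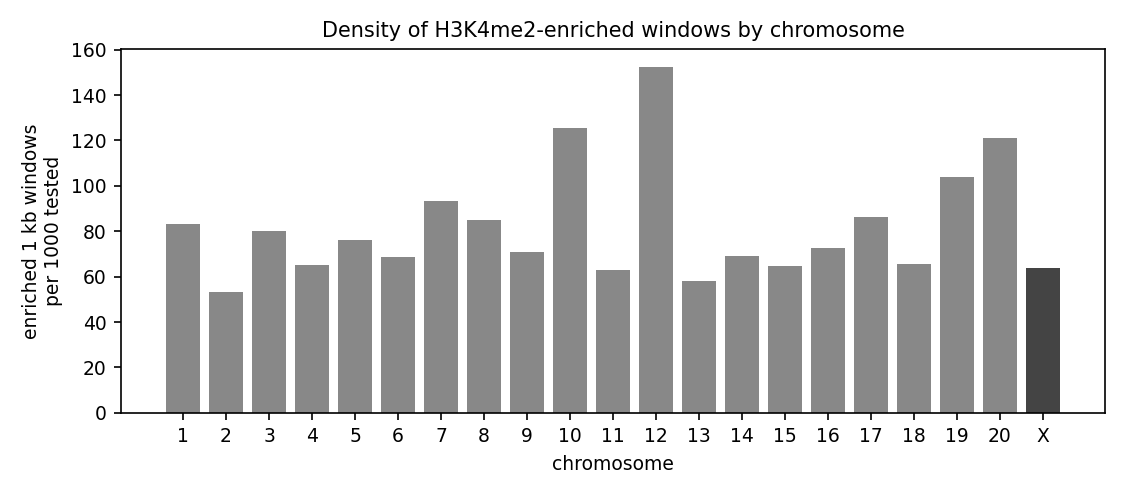
Enriched 1 kb windows per 1000 tested (y axis) for each autosome and X (x axis), from the test over 8 libraries. Chromosome 12 is highest at 153 and chromosome 2 lowest at 53.3, with X at 64.0. Per Mb, which is not drawn, X is lowest at 44.4 and chromosome 2 next at 48.4. X had fewer reads and a smaller share of windows tested than the autosomes, so its values are not directly comparable.

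Nucleosomes protect about 150 bp of DNA from MNase, and IP reads on chromosome 1, taken as a whole or in enriched windows, were spaced at about that length. In enriched windows, the distance from a plus-strand to a minus-strand read start was, between 100 and 250 bp, most frequent at 149 to 152 bp in all 4 IP libraries. Pairs 150 bp apart were 1.19 ± 0.03 times as frequent as pairs 300 to 400 bp apart in the IP, against 1.01 ± 0.02 in the controls (SD, n = 4; two-sided exact permutation p = 0.0286, adjusted 0.0429 over 3 sets of windows). The assignments behind this p ignore the pairing, and exact sign flips within the 4 rats gave p = 0.13, the smallest they allow, here and for the other comparisons of IP with control distances below, except same-strand distances over all of chromosome 1, where p = 1. In the other windows the ratio was 1.07 ± 0.02 in the IP and 1.04 ± 0.01 in the controls (two-sided exact permutation p = 0.0571, adjusted 0.0571). The IP ratio was lower than in enriched windows in all 4 rats, by 0.117 on average, with p = 0.13 by exact sign flips. Enriched windows were called from these same IP reads, so the choice of windows can itself raise their IP ratio and both contrasts. Over all of chromosome 1, without that choice, the ratio was 1.15 ± 0.04 in the IP and 1.04 ± 0.01 in the controls (exact permutation p = 0.0286, adjusted 0.0429). The most frequent distance was 149 to 151 bp there in all 4 IP libraries, but 100 to 199 bp in the other windows. Fragments that abutted, with an end and a start at neighbouring bases, were 2.05 ± 0.44 times as frequent as the same background in IP libraries and 1.07 ± 0.02 times in controls (two-sided exact permutation p = 0.0286). The IP ratio of abutting fragments was 1.89 ± 0.29 in enriched and 2.45 ± 0.71 in other windows, lower in enriched windows in 3 of 4 rats (p = 0.25 by exact sign flips, which cannot go below 0.13). For same-strand distances the largest ratio to the background within the range searched was taken. It was 1.05 ± 0.01 in enriched windows in the IP and 1.02 ± 0.005 in controls (exact permutation p = 0.0286, adjusted 0.0856). The distance of this largest ratio was 154 to 177 bp in the IP and 150 to 202 bp in the controls, so it need not mark a peak. In other windows the largest ratio was lower in the IP of all 4 rats, at 1.02 ± 0.01 against 1.04 ± 0.01 (exact permutation p = 0.0571, adjusted 0.0856). Over all of chromosome 1 it was 1.04 ± 0.01 in both (exact permutation p = 1).

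**Figure D5:**
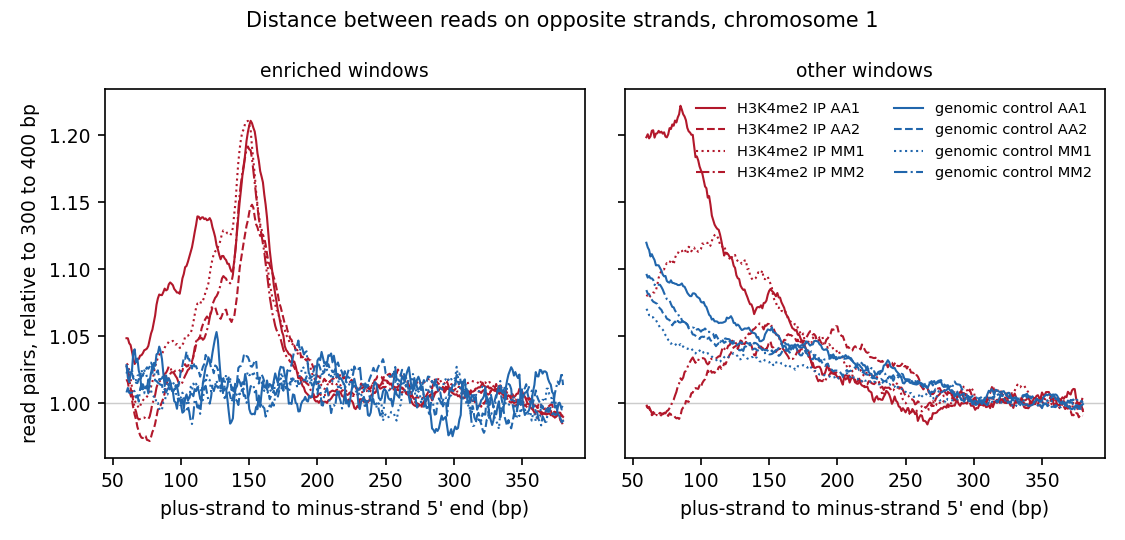
Frequency of distances from plus-strand to minus-strand read starts on chromosome 1 (x axis, bp), relative to the mean at 300 to 400 bp (y axis), in enriched windows on the left and other windows on the right. In enriched windows each IP library is highest at 149 to 152 bp within 100 to 250 bp and the controls lie between 0.996 and 1.03 at 150 bp, while in other windows the IP libraries lie between 1.05 and 1.09 there; abutting fragments are outside the range drawn.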

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

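Of the tests in this part, those of exchanged labels, of a mixture and of the lane were chosen after the results were seen, that of a mixture on 3 more sets of windows after its first value of 2.55, and the test of repeated positions before. Of 80 groups of 4 values examined for a value far from the other 3, 4 had such a value, and chance gives about 1 in 20, or 4.

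Reads at a position already used made up 22.5% of IP reads on average, from 15.6 to 30.6%, against 1.64 to 2.02% of control reads (two-sided exact permutation p = 0.0286, and 0.13 by sign flips within rats, the smallest they allow). They were left out of the comparisons and stood far above the control level. The AA2 IP library stood apart in 2 measures: its mitochondrial share of all reads, 0.00193% against 0.000925 to 0.00109% in the other IP libraries, and its frequency of abutting fragments in enriched windows, 2.32 times the background against 1.72 to 1.79. Chromosome 3 took 6.45% of MM1 control reads, less than the 6.46% of each other control by about 0.01 percentage points. Chromosome 9 took 4.17% of AA1 IP reads against 4.23 to 4.24% in the other IP libraries.

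The AA2 IP library was the least enriched in the shares of reads and in 18 of the 20 named regions. Exchanged labels within the pair are argued against by a share of reads in regions that was 2.03 times higher in the AA2 IP than in its control. Removal of repeated positions is argued against as well: with all reads kept, the AA2 share minus the lowest other IP share was -6.05 percentage points, although the AA2 region set was the largest. A mixture with control-like DNA, as from a less efficient pull-down, cannot be told apart from other sources, since the excess of AA2 over its control as a fraction of that of AA1, in the strongest over the weakest of 3 equal classes of windows, depended on the windows: it was 1.06 (95% bootstrap interval 1.04 to 1.07) in those called in both MM1 and MM2, 1.20 in those called in each rat but AA2, 1.95 in those called in MM1 or MM2 and 2.55 in those fitted from the 3 rats, where a constant fraction gives 1, and over all windows called in AA1, in MM1 or in MM2 it was 1.14 to 1.46 for AA2 against either remaining rat and 0.83 to 1.20 between those 2, taken in both directions. The lane cannot be told apart from AA2, the only IP library on lane 7: its control, alone on lane 8, held 7.57% of reads in the regions, within the 6.85 to 7.85% of the others, which leaves an effect on IP libraries open, and no biological explanation was tested.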

How the results depend on the processing

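The number of enriched windows stayed within 1.5 times of 187367 under each change of block, lane term, duplicates, read shift, scaling, model, read minimum and rats tried, between 139786 with total scaling and 235594 without AA2. Without a rat it was 150932 to 235594 windows and 49251 to 76104 regions. It was 346257 with 500 bp windows, 93302 with 2 kb windows and 76340 at a log2 ratio of at least 2, where regions numbered 29343. A higher threshold lowers the window count by construction. Of the 2 kb windows tested 7.41% were enriched and of the 500 bp windows 11.3%, against 7.71%. A smaller part of the 500 bp windows was tested, 3052422 of 5437770, against 2431677 of 2718891 in the main setting. The median log2 ratio of the tested windows was 0.154, against -0.011. The 500 bp share is therefore of a set with higher ratios and is not directly comparable with 7.71%. Causes other than this selection were not tested. With the lane in the fit, which gives AA2 about as much weight as the other 3 rats together, 155274 were enriched and 81.5% of the 187367 remained. Of these 74.6% remained with total scaling and 78.9 to 98.2% without a rat, and none became depleted in these settings.

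The depleted count of 1193 depended on most choices, and the cause was not tested. It was 2974 with no replicate block, 774 with the lane, 2069 with all reads, 25267 with total scaling, 10743 with limma-trend, 2055 with at least 20 reads and 2844 with at least 1 read per window, 94 with 500 bp windows, 35 at a log2 ratio of -2 or below and 34 at an adjusted p under 0.01. Without a rat it was 76 to 703. No other count of calls moved by over 1.5 times without the block.

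The difference in the share of reads was 17.9 percentage points by the main test and by sign flips within rats, where the exact p was 0.13, the smallest possible, and 16.0 to 20.5 without a rat, where 20 assignments allow no p under 0.1. Mean agreement between rats was 0.379 and rose to 0.505 in 2 kb windows. No chromosome was called with all reads kept either, and sign flips and 3 rats per group could not have called any. The 20 named regions kept their call in all 220 comparisons, and the 5 depleted windows in 40 of 54, with no reversal. Both were chosen as extremes of the main fit on the same reads, so this says nothing of the other regions and windows. The effect of depth on weak enrichment was not tested. DESeq2 and edgeR, and the promoter and gene list alternatives, were not run.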

Other observations

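The tests of strand placement, strand-favouring libraries and splits in this part were chosen after the results were seen, as were the 1 Mb segments and the X ratios, and the test of depleted windows before, but its value without AA2 after. Windows enriched in the IP were gathered in some 1 Mb segments. Among 2689 segments with at least 500 tested windows the median was 59.9 enriched windows per 1000 tested, and the densest 10% held 27.7% of all enriched windows. The densest was on chromosome 7 from 10000001 to 11000000, with 423 of 954 windows enriched, followed by chromosome 20 from 3000001 to 4000000 (299 of 798), chromosome 1 from 95000001 to 96000000 (352 of 987), chromosome 10 from 56000001 to 57000000 (312 of 933) and chromosome 12 from 42000001 to 43000000 (305 of 961). In 12 segments no window was enriched by limma-voom, and 6 of these were on chromosome 13, between 2000001 and 30000000.

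Chromosome X, present once per diploid male genome and in part of the sperm, had control reads at about the level of a single copy. In windows with balanced strands the control median was 6.75 reads per kb on X and 13 on the autosomes, a ratio of 0.519. In 10 kb bins the median X to autosome ratio was 0.557 ± 0.009 in controls and 0.622 ± 0.040 in IP libraries (SD, n = 4), higher in the IP of all 4 rats, with a two-sided exact permutation p = 0.0286, adjusted 0.0857 over 3 measures, and p = 0.13 by sign flips within rats, the smallest they allow. By the same exact permutation test the mean ratio over balanced windows was 0.569 ± 0.012 in controls and 0.573 ± 0.065 in IP libraries (p = 0.914, adjusted 0.914), and that over enriched windows 0.712 ± 0.030 and 0.693 ± 0.122 (p = 0.743, adjusted 0.914).

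Reads in many windows came mostly from the plus strand. In 160875 tested windows over 80% of control reads were on the plus strand, and in 244 under 20% were. Windows over 80% made up 17.2% of tested windows on X and 6.11% on the autosomes, and 1.27% of them were enriched, against 7.71% of all. Of the 244 windows under 20%, 70 (28.7%) were enriched. A library preparation that favours a strand everywhere is argued against, since the plus-strand percent of all control reads lay 2.79 percentage points above that of the median window. The IP libraries, made separately, had 91.1% plus-strand reads in the same windows, which goes with placing reads with several matching places on the forward strand first. Other causes tied to the position in the genome would also give this agreement between IP and control. It therefore does not single out that placement, and reads with several matching places were not counted. No biological explanation was tested; with windows of balanced strands alone, 173238 were enriched.

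Of the 1193 depleted windows 0 lay beside another, and random placement gives 0.098%. In the rat left out, 1207 windows called depleted from the other 3 rats had a median log2 ratio of -0.10 (95% bootstrap interval -0.138 to -0.06), which met the bound set beforehand for counting noise, above -0.2. The bound was applied without each rat only after this value was seen: the median was -0.09 without AA1, -0.06 without MM1 and -0.08 without MM2, also above it, but -0.25 (-0.379 to -0.184) without AA2, which gave 703 of the windows. By rat the medians were -0.17 in AA1, -0.03 in AA2, -0.30 in MM1 and -0.37 in MM2. Counting noise in single windows and a true depletion smaller than called cannot be told apart by these values, since that without AA2 lies between this bound and the -0.5 set against noise.

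IP and control came from the same rats, and 8 of the 35 splits of the 8 libraries into 4 and 4 part all 4 pairs as IP and control do, too few for a share under 0.05. By limma-voom with the rat block 1 of these 8, the real split, gave 187367 enriched and 1193 depleted windows, and the highest of the others gave 0 of each. The 24 splits that part 2 pairs use fewer pairs and also gave 0. In each split but the real one the difference between IP and control is part of the residual spread, so a count of 0 there is no clean value for no change. At least 2-fold and at an unadjusted p under 0.05, the real split gave 191758 windows in its larger direction, the split by lane 132543 and the highest other split, which parts 2 pairs, 136438.

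The share of enriched windows differed with the number of control reads per library: it was 57.9% of the 4851 tested windows with under 5, 11.5% with 5 to 8, 12.95% with 8 to 11, 7.73% with 11 to 14, 4.92% with 14 to 17, 3.19% with 17 to 20, 6.03% with 20 to 50 and 7.84% with 50 or more. The minimum was set on the sum over IP and control, so a window with under 5 was tested only with more IP than control reads, which does not hold for the other classes, where the cause was not tested. With at least 5 control reads per library required, 184493 windows were enriched.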
